A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

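RNA that co-purified with the mRNA export receptor Mex67 or with the mRNA-binding adaptor Npl3 was measured on microarrays in baker's yeast, beside a mock precipitation from cells without a tagged protein. Per the labels' protocols, cells grown in rich medium were divided, kept at 25 °C or 42 °C for 30 min, crosslinked with UV light and lysed, and the lysates were incubated with beads carrying a c-myc antibody and with GFP-Trap beads. The RNA was then extracted and labelled with biotin. The labels name a kit for 3' labelling and a manual for whole-transcript labelling, and which of them was used is not clear, so what a difference between 3' and 5' probe sets or a trend with length means depends on this. The 6 groups (no tag, Mex67 and Npl3, each at both temperatures) hold 1 array each, and the labels give 3 strain entries, so that each precipitated protein comes from a strain of its own. The no tag label names a pair of strains, and whether they were pooled is not stated. There are no replicates, so no p-value was computed and no difference has a replicate check.

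The authors deposited log2 values, 1 per probe set and array. Per the submitters' processing notes, the R package affy was used; its version, the background correction, the normalization method and the summary method are not given in the sources used here. The sorted deposited log2 values of the 6 arrays were compared over a range of lower ranks and a range of upper ranks. They lie close together there, with a spread between arrays of at most 0.07 and 0.09. The middle ranks were not compared in this way. They lie further apart, with array medians over all probe sets from 7.78 (no tag, 25 °C) to 8.22 (Mex67, 42 °C). From the compared ranks, the arrays are taken to have been normalized to each other before deposit. Such a normalization sets the overall level of every array alike, so a precipitate that held more RNA in total than the control does not show as higher values throughout. All differences are therefore relative to the other mRNAs of the same array. Columns were matched to samples by strain number and by the letters S and US, read as stressed (42 °C) and unstressed (25 °C). The labels do not spell these letters out. The reading was checked on the data: in each of the 3 pairs, all 30 heat shock chaperones were higher on the array marked S. The direction of the chaperones themselves is therefore not independent of the reading.

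The table has 10928 probe sets, of which 5716 are for S. cerevisiae genes, 4999 for the fission yeast S. pombe, whose RNA was not in the samples per the labels, and 213 are control or reporter probe sets. The S. cerevisiae probe sets represent 5667 loci. Of these, 5646 were named by locus tag through the RefSeq gene table of assembly R64, strain S288C, and 21 keep the name in the table. Probe sets of the same locus were averaged (47 loci have several). For 87 loci every probe set matches several transcripts, and these were counted but not named. Gene lengths came from the same reference for 5646 loci, and 97.0% of them are multiples of 3, so they are read as coding length.

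A comparison is the difference of log2 values between 2 arrays, or a difference of differences over 4 arrays. A gene was counted when it differed at least 2-fold and lay above the floor in at least 1 array of the comparison. The floor was each array's 95th percentile of S. pombe probe sets, between 5.00 and 5.12, and 99.2% to 99.6% of the loci lay above it on each array. As a yardstick for background, between 0 and 3 of the 4999 S. pombe probe sets differed at least 2-fold between any compared pair of arrays, and 10 or 15 did in the differences of differences. These probe sets are dim, so they show background noise and not the spread between independent precipitations. The number of arrays limits the precision.

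For 18 gene lists, the median log2 difference was set beside 10000 random lists of the same size, matched on mean level in 20 bins. Its percentile among them describes these arrays and is no test. Intervals printed beside medians and ratios come from a bootstrap, in which the genes concerned were drawn again with replacement. They show the spread between genes, which are not independent. They do not cover the spread between precipitations, so they are no test either. The lists were heat shock chaperones, general stress genes, ribosomal proteins, ribosome biogenesis, glycolysis, translation factors, proteasome, mitochondrially encoded mRNAs, nuclear genes of respiration, intron-containing genes other than ribosomal proteins, mRNA export factors, cell wall integrity, histones, amino acid synthesis, membrane and secreted proteins, stable noncoding RNAs, strain markers and mating type genes. The mitochondrially encoded and noncoding lists had 0 measured members, so 16 lists were analysed.

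Named genes followed a rule. Among genes with a symbol of their own above the floor, these were the 8 highest and the 8 lowest log2 differences of at least 1 in size, and up to 4 members of a described list with the largest difference in the direction of its median. MEX67, NPL3 and the heat shock genes HSP104, SSA4, HSP82, HSP26, HSP42 and HSP12 were named whatever their values. The lists, this rule, the comparisons and most alternatives were set before the data were examined. The alternatives were no floor, a floor at each array's median, centring on S. cerevisiae or S. pombe probe sets, quantile normalization, the brightest probe set per gene, values raised to the floor and, for overlaps, a 3-fold threshold. Added after seeing the data were counts without mating type and strain marker genes, leaving out probe sets that match several transcripts, and list medians after the median of each of 5 equal groups of gene length was subtracted.

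The counting was tested on simulated data drawn around the real mean levels of 5667 genes with S. pombe noise, with 200 genes changed. In the heat difference of the Mex67 precipitation, 49 of 50 genes changed 3-fold and 0 of 50 genes changed 1.5-fold were counted. For the Mex67 heat difference over the control, 15 of 5467 unchanged genes were counted as well. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.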

Results

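The experiment asked which mRNAs the export receptor Mex67 and the adaptor protein Npl3 were bound to in growing and in heat-stressed yeast. Mex67 carries mRNA through the nuclear pore, and Npl3 is an SR-like protein that binds transcripts in the nucleus. RNA was precipitated from UV-crosslinked cells of a Mex67 strain, an Npl3 strain and cells without a tag, for which the label names a pair of strains, after 30 min at 25 °C or 42 °C, and each of the 6 precipitates was hybridised to 1 array. Values are the authors' log2 values, normalized between arrays, and no comparison has replicates. The arrays were assigned to temperatures by reading S in the column names as stressed and US as unstressed, which the labels do not spell out. All 30 heat shock chaperones were higher on the S array of each of the 3 pairs. Median values of S. cerevisiae genes lay between 11.13 and 11.18 on all 6 arrays, against 3.96 to 4.02 for the S. pombe probe sets that served as background. The highest values were 15.36 to 15.43.

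**Figure D1:**
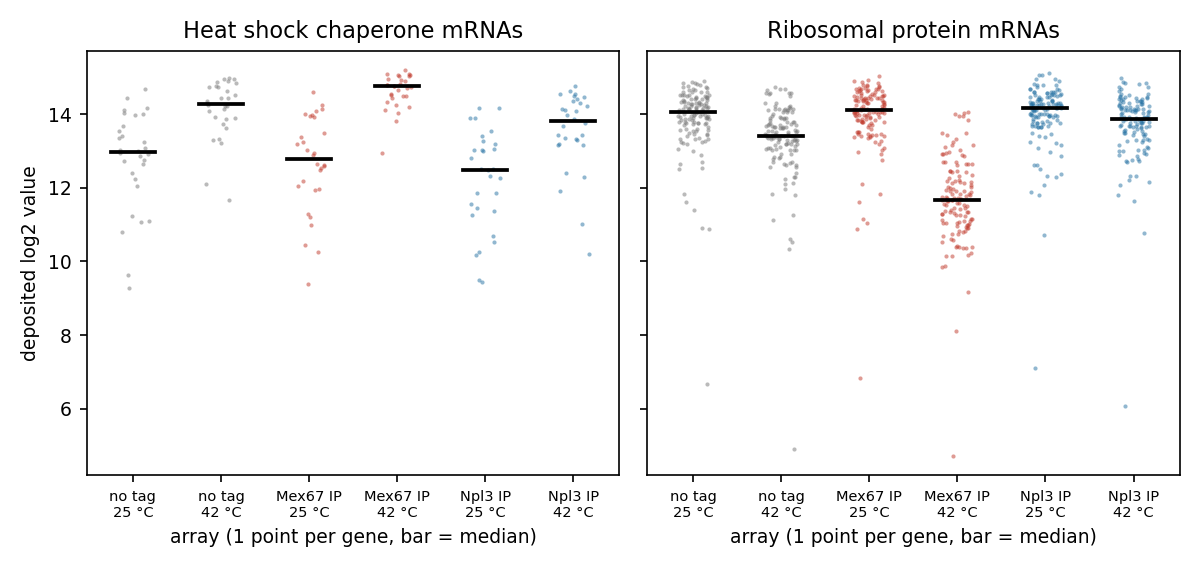
Deposited log2 values (vertical axis) of the 30 heat shock chaperone mRNAs (left) and 130 ribosomal protein mRNAs (right) on each of the 6 arrays, with 1 point per gene and a bar at the median. The median of ribosomal protein mRNAs was 11.67 on the Mex67 array at 42 °C and 13.41 or more on each other array.

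The mRNAs of the precipitated proteins themselves were looked at first. At 25 °C and 42 °C, MEX67 mRNA was at 11.65 and 11.47 in the controls, 11.30 and 11.83 in the Mex67 precipitates and 11.61 and 11.52 in the Npl3 precipitates. NPL3 mRNA was higher in the Npl3 precipitates, at 14.98 and 15.03, than in the controls, at 13.98 and 14.19, or the Mex67 precipitates, at 14.14 and 14.59. The arrays also differed in signs of RNA input and quality. Labelling spikes, RNAs added before labelling, had a median of 6.65 and 6.64 in the controls at 25 °C and 42 °C and 6.35 in the Mex67 precipitate at 25 °C, but 5.01 in the Mex67 precipitate at 42 °C and 5.22 and 5.40 in the Npl3 precipitates. The 3' probe set of actin exceeded its 5' probe set by 0.41, 0.43 and 0.44 on the first 3 of these arrays and by 0.82, 1.19 and 1.10 on the other 3. The same difference for SRB4 was 2.15, 2.31 and 2.09 against 3.02, 3.26 and 3.08, but for SPT15 it was 1.74, 1.67 and 1.53 against 1.77, 1.70 and 1.62, with no such split. The comparisons that cross this split are Mex67 with the control at 42 °C, heat with Mex67 (also over the control), Npl3 with the control at both temperatures, and Mex67 with Npl3 at 25 °C.

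**Figure D2:**
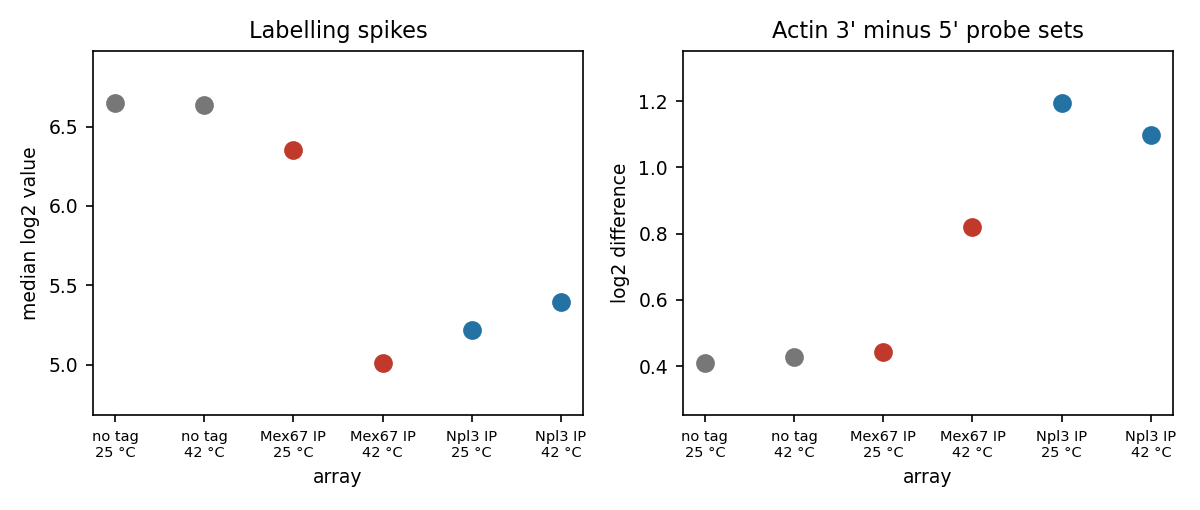
Median log2 value of 36 labelling spike probe sets (left) and log2 difference between the 3' and 5' probe sets of actin (right), with 1 point per array. The Mex67 array at 42 °C and both Npl3 arrays had spikes at or below 5.40, and the other 3 arrays were at or above 6.35.

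Heat in the control precipitate served as the background against which bound mRNAs are read. Chaperone mRNAs were higher at 42 °C: HSP26, a small heat shock protein, by 5.68 on the log2 scale, SSA4, an Hsp70 chaperone, by 3.78, HSP30 by 3.69 and HSP78 by 2.83. HSP104, the disaggregase, was higher by 1.55, HSP82, the inducible Hsp90, by 1.73, HSP42 by 1.78 and HSP12 by 3.41. Of the 30 heat shock chaperones, 15 were at least 2-fold higher and 0 lower, with a median of 0.97, where 95% of random lists had medians between -0.25 and 0.15. Of the 35 general stress genes, 21 were at least 2-fold higher, with a median of 1.14, led by GND2 at 3.78 and HSP12. Genes of amino acid synthesis were divided: 12 of 47 were at least 2-fold higher, among them ARG3 at 5.09, ARG1 at 3.55 and MET6 at 1.88, while the list's median was 0.12, and 0.03 after removal of the trend with coding length.

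Ribosomal protein mRNAs were lower in the heated control in 129 of 130 cases, by a median of -0.53, and 6 were at least 2-fold lower, with RPS28A at -1.38 and RPS22B at -1.31. Histone mRNAs had a median of -0.93 over 9 genes, with HTB2 at -1.35 and HHO1 at -1.33. Cell wall integrity genes had a median of 0.47, with PIR3 at 3.02 and GSC2, a glucan synthase subunit, at 1.74, and proteasome genes a median of 0.35. Over all genes, 378 were at least 2-fold higher and 117 lower, out of 5647, and 155 and 75 with the floor at each array's median, which tests fewer genes. STR3, an enzyme of methionine synthesis, was the highest at 5.93, and SEO1 at 4.12 and BNA2 at 3.95 were among the 8 highest. The pheromone gene MF(ALPHA)2 at -3.25, HO at -2.30, CIS1 at -2.30 and the glucose transporter HXT1 at -2.26 were the lowest.

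In the Mex67 precipitate, heat went with higher chaperone mRNAs and much lower ribosomal protein mRNAs. HSP30 was higher at 42 °C by 5.09, HSP26 by 4.79, HSP12 by 4.36, SSA4 by 3.90, HSP82 by 2.55, HSP42 by 2.42 and HSP104 by 2.22. Of the 30 heat shock chaperones, 23 were at least 2-fold higher and 0 lower, with a median of 1.81. Of the 130 ribosomal protein mRNAs, 123 were at least 2-fold lower and 0 higher, with a median of -2.28, and RPL40B at -3.53, RPS9B at -3.33 and RPS28A at -3.29 were among the 8 lowest genes. On the same pair of arrays the 5.8S ribosomal RNA probe set was at 13.85 at 25 °C and 11.57 at 42 °C, and the median of 17 ribosomal RNA probe sets at 14.56 and 13.71. The Npl3 arrays had ribosomal RNA medians of 13.71 and 13.91. The median of general stress genes was 1.76, with 24 of 35 at least 2-fold higher. TSL1, a subunit of trehalose synthase, was higher by 4.53 and SPI1 by 3.22.

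Ribosome biogenesis factors were lower too, with a median of -0.72, and 14 of 56 were at least 2-fold lower, among them NOP10 at -2.17 and NOP56 at -1.57. Intron-containing genes other than ribosomal proteins had a median of -0.49, with 12 of 45 at least 2-fold lower, such as RIM1 at -2.53 and ASC1, a ribosome-associated protein, at -2.05. Proteasome genes, a list of subunits and their transcription factor RPN4, had a median of 0.59, with RPN4 at 1.25 and PRE4 at 1.14. Cell wall integrity genes had a median of 0.88. Glycolytic mRNAs, among the most abundant, had a median of 0.11, and translation factors one of -0.50, at percentile 13.5. In all, 869 genes were at least 2-fold higher (508 with the floor at the median) and 689 lower, out of 5650. STR3 at 6.02, MET2 at 5.01, YRO2 at 4.51 and SMA1 at 4.48 were also among the 8 highest. The pair of arrays crosses the split in labelling spikes, 6.35 at 25 °C against 5.01 at 42 °C.

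**Figure D3:**
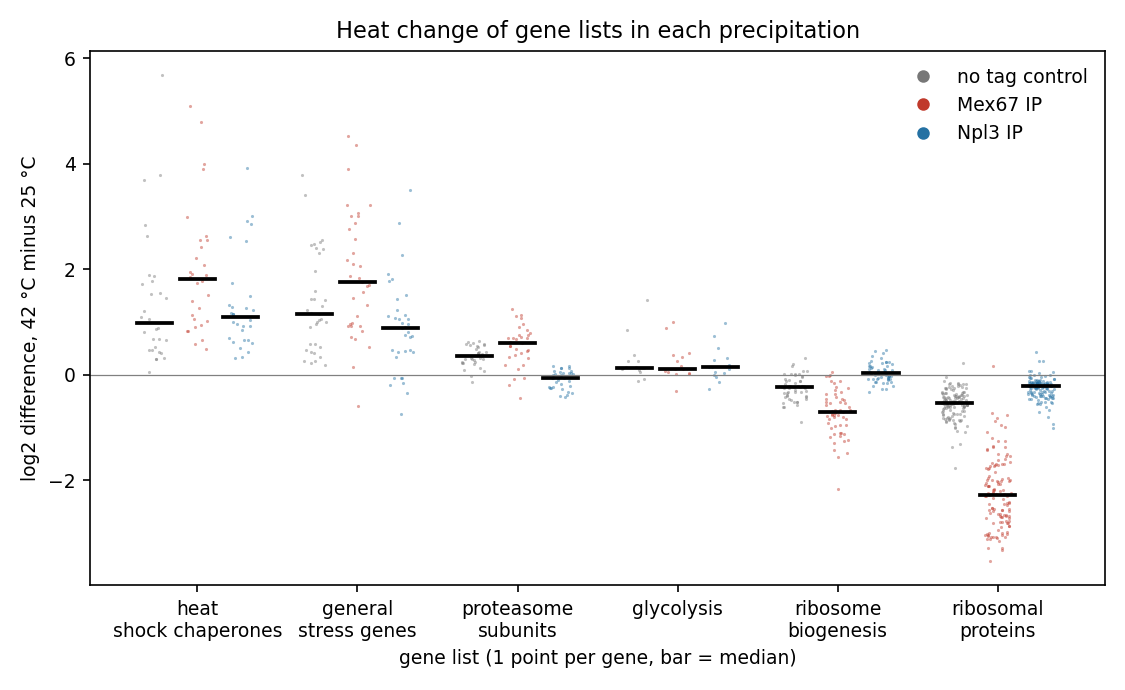
Log2 difference between 42 °C and 25 °C (vertical axis) for the members of 6 gene lists in the no tag, Mex67 and Npl3 precipitates, with 1 point per gene and a bar at the median. Ribosomal proteins had medians of -0.53, -2.28 and -0.22 in that order, and heat shock chaperones 0.97, 1.81 and 1.09.

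The heat difference of the Mex67 precipitate was then taken over that of the control, which again sets the Mex67 arrays with spikes of 6.35 and 5.01 against each other. All 130 ribosomal protein mRNAs lay below 0 and 115 at least 2-fold below, with a median of -1.74, where 95% of random lists had medians between -0.32 and -0.07. RPL40B at -2.79, RPS9B at -2.64 and RPL27B at -2.64 were among the 8 lowest genes. Heat shock chaperones had a median of 0.59, against -0.44 to 0.04 for random lists, and 8 of 30 were at least 2-fold higher. APJ1, a J-domain protein, was at 1.72, CUR1 at 1.51, HSP30 at 1.40 and FES1, an exchange factor of Hsp70, at 1.22. HSP82 was at 0.82, HSP104 at 0.67, HSP42 at 0.64, SSA4 at 0.12, HSP26 at -0.89 and HSP12 at 0.95.

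Among general stress genes the median was 0.67, and 10 of 35 were at least 2-fold higher and 1 lower, with TSL1 at 2.07, SPI1 at 1.78, GAD1 at 1.61 and TPS2 at 1.52. Ribosome biogenesis factors had a median of -0.51, with NOP56 at -1.33, and cell wall integrity genes one of 0.28, with YPS3 at 1.57, which was 0.17 after removal of the length trend. Overall counts were 286 genes at least 2-fold higher (184 with the floor at the median) and 305 lower, out of 5651. FMP48 at 2.60 and the transcription factor gene ADR1 at 2.18 were among the 8 highest, beside mating type genes. HSP26, SSA4 and HSP12 lay at 14.82 to 15.20 in the heated control and the heated Mex67 precipitate, close to the highest value of the arrays, which leaves little room for a difference. On these 2 arrays the chaperone list had medians of 14.28 and 14.75, with 11 and 18 of 30 members among the top 1% of genes. The same limit thus holds for much of that list at 42 °C.

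In the Npl3 precipitate the heat shock mRNAs were again higher at 42 °C, with HSP26 at 3.92, HSP12 at 3.51, SSA3 at 2.91, HSP30 at 2.85, HSP82 at 2.54, HSP104 at 1.32 and HSP42 at 1.14. SSA4 was at 11.36 at 25 °C and 14.36 at 42 °C. Of the 30 chaperones, 16 were at least 2-fold higher, with a median of 1.09. For general stress genes the median was 0.88, with 14 of 35 at least 2-fold higher, such as SPI1 at 2.88 and ALD3 at 2.27. Ribosomal protein mRNAs had a median of -0.22, and 1 of 130 was at least 2-fold lower. Amino acid synthesis genes had a median of -0.35, with MET17 at -2.81 and MET6 at -1.20.

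Proteasome genes had a median of -0.06, ribosome biogenesis factors one of 0.03 and cell wall integrity genes one of 0.41. Histones had a median of -0.51, and all 9 were below 0. Only 119 genes were at least 2-fold higher and 78 lower, out of 5634 (64 and 40 with the floor at the median), and both arrays lie on the same side of the labelling split. FIG1 and PRM6, genes of the pheromone response, were the lowest at -4.08 and -3.27.

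Over the control, the heat difference of the Npl3 precipitate was near 0 for heat shock chaperones, with a median of 0.02 at percentile 33.8 (-0.04 when centred on S. pombe), and 2 of 30 were at least 2-fold lower. HSP82 was at 0.81, CPR6 at 0.72 and KAR2 at 0.71, and HSP26 at -1.76, SSA4 at -0.78 and HSP42 at -0.64. HSP104 was at -0.23 and HSP12 at 0.10. HSP26 lay at 9.28 in the control and 10.70 in the Npl3 precipitate at 25 °C, but at 14.96 and 14.62 at 42 °C, near the top of the scale. The chaperone median of the heated control was 14.28, which limits how far these differences can be read. Amino acid synthesis genes were lower, with a median of -0.57 and 15 of 47 at least 2-fold lower, such as ARG3 at -4.40, MET17 at -4.22, ARG1 at -4.07 and MET6 at -3.08. ARG3 and ARG1 differed less than 2-fold with heat in the Npl3 precipitate, with levels of 12.15 and 12.84 for ARG3 and 13.79 and 13.27 for ARG1, while the control had 7.24 and 12.33 for ARG3 and 10.43 and 13.98 for ARG1. The general stress median was -0.44, with GND2 at -2.27 and PHM7 at -1.81.

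All 33 proteasome genes lay below 0, with a median of -0.41, and 124 of 130 ribosomal protein mRNAs lay above 0, with a median of 0.27. Ribosome biogenesis factors had a median of 0.26, and 50 of 56 were above 0. In total 64 genes were at least 2-fold higher and 243 lower (117 with the floor at the median), out of 5649, with STR3 lowest at -5.73 and PHM6 at 2.56 and CWP1 at 2.17 among the highest. After removal of the length trend, the ribosomal protein median was 0.15.

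At 25 °C the Mex67 precipitate resembled the control: 42 genes were at least 2-fold higher and 37 lower, out of 5632 (21 and 23 with the floor at the median), and the correlation across 5667 genes, which are not independent, was 0.97. Mating type genes led both ends. The alpha pheromone genes MF(ALPHA)1 at -7.82 and MF(ALPHA)2 at -7.18 and the receptor gene STE3 at -6.88 were the lowest, while STE2 at 5.36, BAR1 at 4.69, AGA2 at 3.39 and MFA2 at 3.17 were among the 8 highest. MET17 at -5.36 and LEU2 at -4.30, genes often deleted in laboratory strains, were low too, and URA3 was at -1.67. The mating type list had a median of 1.87 over 13 genes that went both ways, and the 9 strain marker genes one of -0.19. Per the labels the Mex67 and no tag samples come from different strains. With Npl3 at 25 °C the mating type genes named here went the same ways. There MF(ALPHA)1 was at -6.40, STE3 at -5.35, STE2 at 5.37 and BAR1 at 4.87. These differences are therefore read as a difference in mating type between the strains and not as binding.

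Beyond mating type and strain marker genes, general stress genes were lower in the Mex67 precipitate at 25 °C, with a median of -0.56. At least 2-fold lower were 10 of 35, such as SOL4 at -1.76, SPI1 at -1.49 and TSL1 at -1.32. HSP12 was at -1.16, HSP26 at 0.97, HSP82 at -0.46, HSP42 at -0.34, HSP104 at -0.26 and SSA4 at 0.23. Among mRNA export factors, with a median of 0.17, NUP42, a nucleoporin, was at 1.87. Ribosomal protein mRNAs had a median of 0.07, which was -0.02 after removal of the length trend, amino acid synthesis genes one of -0.28 and membrane and secreted proteins one of -0.27.

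At 42 °C the Mex67 precipitate differed more from the control, with 394 genes at least 2-fold higher (257 with the floor at the median) and 327 lower, out of 5650. Ribosomal protein mRNAs were lower in 130 of 130 cases and at least 2-fold lower in 111, with a median of -1.65. RPL40B at -2.78 and AAH1, an adenine deaminase gene, at -2.76 were among the 8 lowest, and RPS7A and RPL25 were both at -2.62. All 30 heat shock chaperones lay above 0, with a median of 0.38 and 3 at least 2-fold higher: APJ1 at 1.71, CUR1 at 1.27 and HSP30 at 1.17. HSP104 was at 0.41, HSP82 at 0.36, SSA4 at 0.35, HSP42 at 0.30, HSP26 at 0.08 and HSP12 at -0.21.

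General stress genes there had a median of 0.04, ribosome biogenesis factors one of -0.37, intron-containing genes one of -0.30 and amino acid synthesis genes one of -0.39. NUP42 was at 2.00, and SAC3 at 1.09 and NAB2 at 1.07 were further export factors at least 2-fold higher. MET17 at -7.64, LEU2 at -5.33, MF(ALPHA)1 at -6.68 and STE2 at 2.78 were again at the ends. YMR317W at 2.49, YDR246W-A at 2.48, NAT4 at 2.41, CTA1, peroxisomal catalase, at 2.29 and BIL2 at 2.29 were also among the 8 highest. The arrays cross the labelling split, 6.64 against 5.01.

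The Npl3 precipitates differed from the control in many more genes at both temperatures than the Mex67 precipitates did. They come from a strain of their own, so a difference between strains cannot be told apart from binding in these counts. At 25 °C 1019 genes were at least 2-fold higher and 853 lower, out of 5639, and at 42 °C 1057 and 1096, out of 5648. Nuclear genes of respiration were higher, with medians of 1.01 and 0.85, and 17 and 14 of 34 were at least 2-fold higher. COX7 was at 2.93 and 3.04, ATP15 at 2.37 and 2.40 and QCR10 at 2.58 and 2.35. Membrane and secreted proteins were lower, with medians of -1.06 and -1.11, and 24 and 25 of 39 were at least 2-fold lower. AGP1, an amino acid permease, was at -2.03 and -2.90, and PDR5, a drug transporter, was at -2.81 at 25 °C.

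Both groups were set beside coding length. The rank correlation with coding length across 5646 genes, which are not independent, was -0.43 at 25 °C and -0.47 at 42 °C, and genes of up to 656 bp had medians of 0.78 and 0.86 against -0.59 and -0.70 for genes of at least 2103 bp. After removal of this trend the respiration medians were 0.36 and 0.03 and the membrane and secreted medians -0.73 and -0.66. Both comparisons also cross the labelling split, with spikes of 6.65 and 6.64 in the controls against 5.22 and 5.40.

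**Figure D4:**
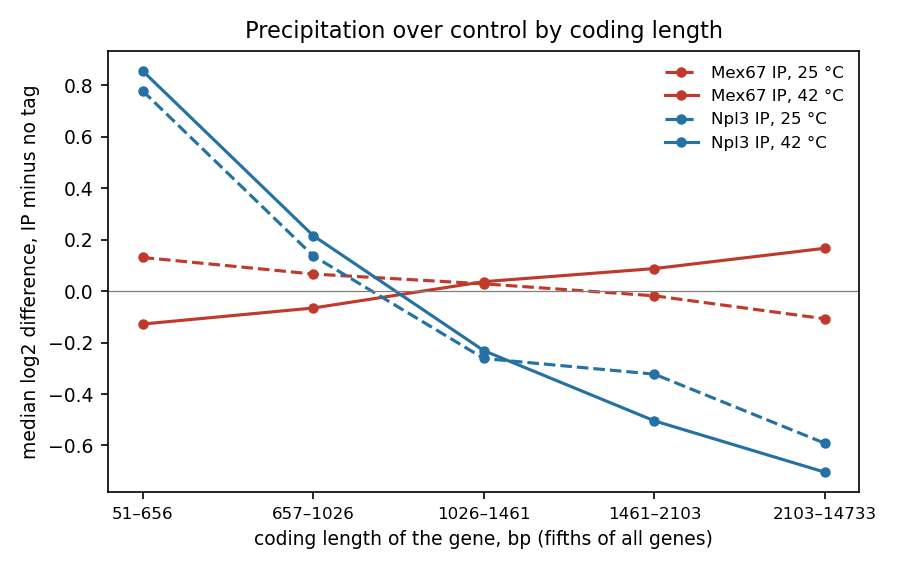
Median log2 difference between each precipitate and the control at the same temperature (vertical axis) for 5 equal groups of genes by coding length in bp (horizontal axis), with 1 line per precipitate and temperature. The Npl3 lines go from 0.78 and 0.86 for the shortest genes to -0.59 and -0.70 for the longest, and the Mex67 line at 42 °C goes from -0.13 to 0.17.

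Heat shock chaperones were lower in the Npl3 precipitates than in the control, with medians of -0.76 at 25 °C and -0.62 at 42 °C, the second of which was -0.16 without the length trend. At 25 °C CUR1 was at -1.73, APJ1 at -1.54, HSP82 at -1.45, HSP104 at -0.89 and HSP12 at -0.25, while HSP26 was at 1.42, HSP42 at 0.45 and SSA4 at 0.28. At 42 °C HSP78 was at -1.72, HSP104 at -1.12, HSP82 at -0.64, SSA4 at -0.49, HSP26 at -0.34, HSP42 at -0.18 and HSP12 at -0.15. General stress genes had medians of -0.59 and -0.77, with GSY2, a glycogen synthase, at -1.72 and -2.65. Amino acid synthesis genes had medians of -0.46 and -0.85, with GDH1 at -2.50 and -2.81, and the first of these medians was -0.23 without the length trend. At 25 °C 5 of the 47 were at least 2-fold higher, and ARG3 at 4.91 was among the 8 highest genes.

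Ribosomal protein mRNAs had medians of 0.06 and 0.33 in the Npl3 precipitates, which were -0.24 and 0.02 without the length trend. Intron-containing genes had medians of 0.25 and 0.29. At each temperature 15 of 45 were at least 2-fold higher, such as SUS1 at 2.81 and 2.80 and MMS2 at 2.51 and 2.39. At least 2-fold lower were 2 at 25 °C and 4 at 42 °C, and 20 and 18 lay below 0. Without the length trend the intron medians were 0.03 and 0.11. NPL3 mRNA itself was at 1.01 and 0.84 and MEX67 at -0.04 and 0.06. QDR2 at -4.62 and -5.49 was among the 8 lowest at 25 °C and 42 °C. So were PRM8 and MST27, which lay at 10.06 and 9.02 in the control at 25 °C and below the floor on both Npl3 arrays, so that no size of difference is given. On the Mex67 arrays at 25 °C and 42 °C, PRM8 lay at 10.22 and 11.02 and MST27 at 8.82 and 9.87. PRM8 and MST27 were thus at background in the Npl3 strain only, and they are not read as binding. Mating type genes led the list at both temperatures, with AGA2 at 5.89 and 6.01 and MF(ALPHA)1 at -6.40 and -6.27. Per the labels the Npl3 and no tag samples come from different strains, so these are not read as binding. LSM8 at 5.02 and SRN2 at 4.06 were among the 8 highest at 42 °C.

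Mex67 and Npl3 precipitates were compared directly, without the control arrays. At 42 °C ribosomal protein mRNAs were lower with Mex67, by a median of -2.09, and 113 of 130 were at least 2-fold lower, such as RPL40B at -3.80 and RPL37A at -3.59. Heat shock chaperones were higher with Mex67, with a median of 0.95 and 12 of 30 at least 2-fold higher, led by APJ1 at 2.80, CUR1 at 2.74, HSP78 at 2.53 and HSP30 at 2.19. HSP104 was at 1.53, HSP82 at 1.00, SSA4 at 0.84, HSP42 at 0.48, HSP26 at 0.43 and HSP12 at -0.06. The general stress median was 0.79, with PHM7 at 3.04 and RTC3 at 2.81. Respiration genes had a median of -1.21, ribosome biogenesis factors one of -0.48 and membrane and secreted proteins one of 0.87.

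At 25 °C the ribosomal protein median between Mex67 and Npl3 was 0.04, and it was -0.01 without probe sets that match several transcripts. Heat shock chaperones had a median of 0.65, with APJ1 at 1.53, CUR1 at 1.49, HSP82 at 0.99 and HSP104 at 0.63, and HSP12 at -0.91, HSP42 at -0.79, HSP26 at -0.44 and SSA4 at -0.06. For general stress genes it was -0.15, and -0.27 without the length trend, with DDR2 at -4.27. Respiration genes had a median of -1.07 and membrane and secreted proteins one of 0.89, with PHO84, a phosphate transporter, at 3.59.

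Counts between Mex67 and Npl3 were 684 higher and 858 lower out of 5641 at 25 °C (448 and 567 with the floor at the median) and 1273 higher and 1140 lower out of 5649 at 42 °C. The rank correlation with coding length was 0.40 and 0.50, and without this trend the medians at 42 °C were -1.61 for ribosomal proteins, 0.52 for heat shock chaperones, -0.18 for respiration, -0.82 for ribosome biogenesis and 0.25 for membrane and secreted proteins, and at 25 °C -0.63 for respiration, 0.44 for membrane and secreted proteins and 0.41 for heat shock chaperones. The arrays at 25 °C cross the labelling split, 6.35 against 5.22, and those at 42 °C do not. URA3, a strain marker gene, was among the 8 lowest genes at both temperatures, at -4.71 and -5.70. PRM8, MST27 and QDR2 were among the 8 highest at both. Per the labels the Mex67 and Npl3 samples come from different strains, so differences between strains may enter these counts and medians as well.

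Genes that were at least 2-fold above the control with both proteins were counted. There were 22 such genes at 25 °C and 117 at 42 °C, where lists drawn independently would share 7.54 and 73.7, and 17 and 64 genes were below the control with both, against 5.61 and 63.5. At a 3-fold threshold there were 10 and 20 above and 5 and 6 below. Both proteins were compared with the same control array. Unchanged precipitates simulated against it shared 0.000 genes on average in each case, but the simulation draws only background noise, which hardly ever reaches 2-fold, and leaves out the spread between precipitations and the difference between strains, so it is no usable reference for these counts. Between temperatures, 33 of 42 genes above the control with Mex67 at 25 °C were also above it at 42 °C, and 805 of 1018 with Npl3. Lists drawn independently would share 2.92 and 190.9. Of the genes below the control at 25 °C, 9 of 37 with Mex67 and 687 of 853 with Npl3 were also below it at 42 °C, against 2.15 and 165.5. The same strains are compared at both temperatures, so a fixed difference between strains recurs too. With Npl3 both comparisons also cross the labelling split. These overlaps are therefore not read as repeated binding.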

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

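The tests of explanations below were chosen only after the results were seen.

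For 4 gene lists fixed before the data were examined, the heat difference over the control lay outside the middle 95% of random lists in opposite directions for the 2 proteins. Ribosomal proteins had medians of -1.74 with Mex67 and 0.27 with Npl3, and ribosome biogenesis factors -0.51 and 0.26. General stress genes had 0.67 and -0.44, and proteasome genes 0.17 and -0.41. Before the control was subtracted, medians in the control, Mex67 and Npl3 were -0.53, -2.28 and -0.22 for ribosomal proteins. For general stress genes they were 1.14, 1.76 and 0.88, for ribosome biogenesis -0.24, -0.72 and 0.03 and for the proteasome 0.35, 0.59 and -0.06. The standard deviation over all genes was 0.63, 1.02 and 0.45. Opposite signs over the control can thus arise where heat differences have the same sign but another size. For general stress genes, Mex67 against the control had medians of -0.56 at 25 °C and 0.04 at 42 °C. The 0.67 thus lies mainly in the arrays at 25 °C and not in a higher level at 42 °C. The Mex67 and control arrays come from different strains at both temperatures, and the cause of the difference at 25 °C was not tested. The difference between the proteins was not tested, since each group is 1 array, and both share the control arrays. Random lists include ribosomal protein genes. For the proteasome with Mex67, 95% of them had medians between -0.41 and 0.05, mostly below 0, so a small positive median lies outside easily.

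Ribosomal protein mRNAs stood lowest in the Mex67 precipitate at 42 °C, where the 5.8S ribosomal RNA was lower as well, at 11.57 against 13.85 at 25 °C. An effect shared by the arrays with low labelling spikes would lower these mRNAs on the Npl3 arrays too, which lie on the same side of the split. There the lower of the 2 medians against the control was 0.059, and -0.24 without the length trend (95% interval -0.32 to -0.11). All intervals in this paragraph are over genes, which are not independent, and leave out the spread between precipitations. The Mex67 median at 42 °C without that trend was -1.58, so no equal drop was seen on the Npl3 arrays. These arrays also carry the binding of Npl3 and another strain, either of which could offset a shared drop. The size of a shared part is therefore not bounded. Short genes as a class did not account for it, as the median over the control was -1.60 after the length trend was removed. A wider scale of the cells' own heat response did not account for all of it. In the same range of mean level and control heat difference, 167 other genes had a median of -0.51 in the control. With Mex67 their median was -0.84 (95% interval -0.95 to -0.72), and 39.5% of them were at least 2-fold lower. The ribosomal proteins had -2.28 with Mex67 (-2.35 for the 61 of them in that range). A wider scale was thus seen outside the list too and may make up a part of the ribosomal protein difference. An earlier version of that last test compared ratios of the Mex67 to the control heat difference, 4.27 for ribosomal proteins against 1.86 for heat shock chaperones, and was replaced because chaperone mRNAs lie near the top of the scale at 42 °C; at mean levels under 13 the ratio was 4.18 (95% interval 3.25 to 5.26) for 25 ribosomal proteins, 1.22 (1.13 to 4.44) for 8 chaperones, 2.16 (1.14 to 3.67) for 14 cell wall integrity genes and 1.53 (1.06 to 1.99) for 26 general stress genes, so that only the last interval lay apart from that of the ribosomal proteins. What stays open, each untested, includes a lower cellular level of these mRNAs in the Mex67 strain, since RNA before precipitation was not analysed here, a different share of background RNA in the Mex67 precipitates at 25 °C and 42 °C, and, as a hypothesis from the same data, less binding of ribosomal protein mRNAs by Mex67 in heat.

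Outside the measurement of yeast genes, some reporter probe sets, which the table lists apart from the yeast genes, were far above their level in the no tag arrays. In the Mex67 arrays 3 of them exceeded the control by 6.998, 5.83 and 7.56 at 25 °C and by 6.97, 5.66 and 7.25 at 42 °C. In the Npl3 arrays another was higher by 5.97 at 25 °C and 5.21 at 42 °C. The identifiers of these probe sets point to sequence records that were not looked up here, so what they represent was not determined.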

How the results depend on the processing

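Removing the trend with coding length, counting without mating type and strain marker genes, and leaving out probe sets that match several transcripts were tried only after the data were seen. Of the list medians under the alternatives, 1187 stayed within their spread, 42 moved and 3 that had lain outside the middle 95% of random lists changed sign; counting all medians, however small, 35 of 1232 changed sign, 21 of them without the length trend; of the counts, 186 stayed within 1.5 times and 12 moved, and 4 of 8 overlaps moved. No count or list median moved with centring on S. cerevisiae genes, the brightest probe set or values raised to the floor. These settings could change little. Array medians of these genes already lay between 11.13 and 11.18, only 47 of 5667 loci had several probe sets, and at least 99.2% of loci lay above the floor. Quantile normalization met arrays already close at the compared ranks, but it changed the balance of directions. The share of counted genes that were higher went from 76.4% to 67.4% for heat in the control. For the Npl3 heat difference over the control it went from 20.8% to 30.7%. Without the length trend, 39 of 176 list medians moved and 2 changed sign from outside the middle 95% of random lists. No count or overlap moved with no floor, and no count without mating type and strain marker genes. List medians were not run under these. Leaving out the 13 mating type and 9 strain marker genes could hardly move a large count, and genes such as PRM8 and MST27 were kept. It therefore does not show how far differences between strains enter the counts. With a floor at each array's median, which tests fewer genes, Mex67 against the control gave 21 higher and 23 lower at 25 °C and 257 higher at 42 °C, and Mex67 against Npl3 at 25 °C gave 448 higher and 567 lower. Under that floor, heat gave 155 higher and 75 lower in the control, 508 higher with Mex67, and 64 higher and 40 lower with Npl3, and over the control 184 higher with Mex67 and 117 lower with Npl3. A 3-fold threshold, stricter by construction, left overlaps of 10 higher and 5 lower at 25 °C and 20 and 6 at 42 °C. For heat in the control, quantile normalization gave a glycolysis median of 0.077, and centring on S. pombe gave -0.48 for ribosomal proteins and -0.18 for ribosome biogenesis. Without probe sets that match several transcripts, the ribosomal protein median of Mex67 against Npl3 at 25 °C turned to -0.0093. Without the length trend, Npl3 against the control had medians at 25 °C and 42 °C of -0.24 and 0.015 for ribosomal proteins, 0.0045 and 0.41 for ribosome biogenesis, 0.36 and 0.033 for respiration, 0.16 and 0.13 for mRNA export, -0.96 and -0.75 for histones, -0.23 and -0.58 for amino acid synthesis and -0.73 and -0.66 for membrane and secreted proteins, with -0.16 for heat shock chaperones at 42 °C and -0.15 for glycolysis at 25 °C. Of these, ribosomal proteins and ribosome biogenesis at 25 °C, histones at 42 °C and mRNA export at both temperatures changed sign. Mex67 against Npl3 then had 0.26 and -1.61 for ribosomal proteins, 0.13 and 0.10 for glycolysis, -0.63 and -0.18 for respiration, 0.97 and 1.17 for histones and 0.44 and 0.25 for membrane and secreted proteins, and at 42 °C 0.52 for heat shock chaperones, -0.82 for ribosome biogenesis, -0.45 for translation factors, -0.023 for mRNA export and 0.18 for amino acid synthesis, with a changed sign for translation factors and mRNA export. Mex67 against the control then had -0.020 for ribosomal proteins at 25 °C (sign changed) and -0.13 for glycolysis at 42 °C. For heat, ribosomal proteins then had -0.40 in the control, -2.07 with Mex67, -1.60 with Mex67 over the control and 0.15 with Npl3 over the control, and with Mex67 respiration had 0.27 (0.19 over the control), mRNA export -0.21 and membrane and secreted proteins -0.34, with a changed sign for respiration and for membrane and secreted proteins. The cause of these shifts was not tested beyond the trend that was removed. No paired analysis was possible because each comparison, kept to a precipitate or to a temperature, has 1 array per group and comes from no test. A heat effect common to the 3 precipitates, for which the 3 strains would form 3 pairs, was not among the comparisons and was not tested. Signal over background limits genes near the floor, and the top of the scale limits the brightest ones.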

Other observations

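The tests in the last 2 paragraphs were chosen only after the results were seen.

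Lists without a clear shift were also measured. Glycolytic mRNAs had medians of -0.04 and -0.07 in the Mex67 precipitates against the control at 25 °C and 42 °C and -0.41 and -0.33 in the Npl3 precipitates. Translation factors had medians of 0.02, -0.36, -0.40 and -0.29 in the same order, and mRNA export factors 0.17, 0.22, -0.13 and -0.29. Without the length trend the Npl3 medians at 25 °C and 42 °C were 0.16 and 0.13 for export factors, and at 25 °C -0.15 for glycolysis and -0.090 for translation factors. Histones were lower at 42 °C in the Mex67 precipitate too, with a median of -0.72, which was -0.27 without the length trend. At 25 °C and 42 °C the 5.8S ribosomal RNA probe set was at 14.08 and 13.78 in the controls and 12.73 and 13.09 in the Npl3 precipitates.

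Short mRNAs were higher in the Npl3 precipitates, with a rank correlation of -0.43 between coding length and the difference to the control at 25 °C. If fragmented RNA read as 3' bias were the cause, the Mex67 array at 42 °C, with its larger 3' to 5' difference for actin, should be lower for long genes, but its heat difference over the control had a rank correlation of 0.29 with length. Likewise, if the labelling split were the cause, that array should be lower for long genes than the control at 42 °C, and the rank correlation was 0.16. Only that 1 array bears on both, so neither is excluded, and the strain background cannot be told apart from the precipitated protein because no untagged array of the Npl3 strain was analysed here (its value is the -0.43 above). A preference of Npl3 itself for short transcripts was not tested.

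The Mex67 precipitate at 25 °C was close to the control, with a correlation of 0.97 across genes. The mating type genes argued against both arrays coming from the same strain, with a median absolute difference of 3.76 between the arrays. These genes also argued against an exchange of the 2 arrays. Each array lay closer to its own strain's array at 42 °C than to the other's, by 2.35 for Mex67 and 1.70 for the control. For the control the 95% interval was 0.28 to 2.78. It is over genes, which are not independent, and leaves out the spread between precipitations. Little RNA above background in the precipitate is a candidate explanation: the labelling spikes of this array lay -0.30 from those of the control, where a lower value is taken to mean more sample RNA per spike. The spikes of this array exceeded those of the Npl3 array at 42 °C, 6.35 against 5.40, by less than the bound of 1 set for a clear separation, so this cannot be told apart from binding in proportion to abundance.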
